A study of Rattus norvegicus with 12 samples.

How the data were processed

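Gene expression was measured with 1-colour Affymetrix arrays, which carry short probes grouped into probe sets, in right and left atrial appendages of male Sprague-Dawley rats, 28 days after an aorto-caval shunt or a sham operation. Per the labels, total RNA was extracted on columns, each RNA sample was a pool of 2 tissues, and biotinylated cRNA was made and hybridised to 1 array per pool. The 12 arrays fell into 4 groups of 3 (right atrium sham, right atrium shunt, left atrium sham, left atrium shunt), taken from the sample titles. The same titles gave the replicate numbers. Per the labels, the source of each sample was right or left atrial tissue, while the tissue entry of the same samples names ventricles besides atria.

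The authors deposited log2 expression values per probe set, 1 column per array, made with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of each probe set. The RMA version, the software around it and the scanner settings are not given in the sources used here. Quantile normalization gives all arrays nearly the same distribution of values: the array medians lay between 5.44 and 5.47. A change shared by most transcripts is therefore not visible in these values, and values near the top of the scale (highest 14.43) are compressed.

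Of 31099 probe sets, the 57 control probe sets were left out and 31042 were tested. The annotation supplied for the array named 1 gene for 20826 of these, several genes for 436 and none for 9780. No gene was named from a probe set with several genes, and the named probe sets covered 14217 genes. Where several probe sets named a gene, the one with the highest mean over the 12 arrays stood for it, and the text says where another probe set of a gene was called in the opposite direction in a comparison described for that gene. All deposited columns belonged to a sample.

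The values were used as deposited, with no further normalization and no filter. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, so that all groups shared an estimate of the spread. The comparisons were shunt minus sham in the right atrium, in the left atrium and averaged over both; the left minus right difference of those effects (the interaction); and left minus right in sham and in shunt animals. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 31042 probe sets, and the threshold was an adjusted p of 0.05. Every adjusted p of a gene below comes from this limma fit. Changes are log2 differences with the standard error (SE) of the fit, and a log2 change of 1 is 2-fold.

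Gene lists for pathways and for cell types were fixed before the data were examined. The 37 lists with at least 5 measured members were tested with limma's camera, which compares a list with all other genes, on 1 probe set per gene, with a preset inter-gene correlation of 0.01 and adjustment over the 37 lists within a comparison. The test was repeated with the correlation estimated from the residuals, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. For each list the members past the threshold over all probe sets were counted, and also those past it when adjusted over the list alone. The erythrocyte list had 4 measured members and was not tested.

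The genes named were fixed by a rule written before the data were examined: for each of the shunt comparisons in 1 atrium and for left minus right in sham, the 12 largest rises and 12 largest falls among genes past the threshold whose groups of arrays did not overlap; for the interaction, genes past the threshold, or the 10 with the smallest p where fewer passed; up to 4 members per list; and a small set named whatever its values, from which genes without a probe set of their own are not analysed here. Genes chosen later are said to be so.

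The scripts were tested on simulated data. In a simulation of the right atrium shunt comparison with 200 of 31042 probe sets changed, 51.6% of those changed by 0.5 log2, 90.4% of those changed by 1 and 98.5% of those changed by 2 were called, and 5.81% of the 172 calls were false. A list shifted by 0.3 log2 was the only 1 of 37 called. The simulated genes varied independently, so this does not test the calls of lists whose genes move together.

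The alternatives tried were leaving out dim probe sets, quantile normalization again, subtraction of array medians, eBayes with trend and robust options, array weights, a fit of only the groups compared, the replicate number as a block, 1 probe set or the mean of all probe sets per gene, and leaving out each array in turn. A further alternative, chosen after seeing the data, kept only replicate 1 of the right atrium shunt group. For the named genes, the fits of only the groups compared and of 1 probe set per gene were added then too. With 1 array left in the right atrium shunt group a fit loses power whatever that array holds, and no fit kept only replicate 2 or 3. Its lost calls therefore decide nothing about replicate 1, so apart from summary totals only its effect sizes are given. No array was a copy of another. Scan dates and batches were not used here. The number of arrays, 3 per group, limits the precision of every value.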

Results

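Transcripts were measured in the right and left atrial appendages of rats 28 days after an aorto-caval shunt, a connection between the large abdominal vessels that overloads the heart with volume, or after a sham operation. There were 3 arrays in each of 4 groups, each array holding a pool of 2 tissues, and p-values measure only the spread between these pools. The values were log2 RMA values of 31042 probe sets. The first principal component, 60.5% of the variance, parted all left from all right arrays. Left atrium shunt replicate 3 stood apart from its group: on component 2 it lay at -26.70, against 14.95 and 13.62 for the other 2 arrays, and its mean correlation with them was 0.989, against 0.992 and 0.993 for theirs.

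In the right atrium, the question was what volume overload changed in the chamber that receives the shunted venous blood. Acta1, the skeletal muscle actin of the fetal heart, rose by 1.59 ± 0.14 on the log2 scale (SE, n = 3 pools per group, adjusted p = 0.000341). Myh7, the slow beta myosin heavy chain, rose by 1.48 ± 0.22 (adjusted p = 0.0068). Matrix genes rose too: Col8a1, a short-chain collagen, by 1.99 ± 0.37 (adjusted p = 0.018), and the matricellular genes Ccn5 by 1.55 ± 0.12 (adjusted p = 0.000193) and Postn (periostin) by 1.48 ± 0.21 (adjusted p = 0.00496). Ltbp2, a matrix protein of elastic fibres, rose by 1.20 ± 0.19 (adjusted p = 0.00768). Igfbp3, a carrier of insulin-like growth factors, fell by 1.35 ± 0.10 (adjusted p = 0.000126). Kcna5, the channel of the ultrarapid atrial potassium current, fell by 0.92 ± 0.14 (adjusted p = 0.00839).

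Other large rises were Sbsn (1.89), Pilra (1.59), Rpl3l (1.5), a ribosomal protein of striated muscle, Myl3 (1.45), Myl2 (1.42) and the homeobox gene Meox1 (1.23). With replicate 1 as the only right atrium shunt array, an alternative chosen after seeing the data, Rpl3l was 0.44, Myl3 0.65 and Myl2 0.51. None of these 3 passed without right atrium shunt replicates 2 or 3 or any 1 right atrium sham replicate. Other large falls were Gpr15lg (-1.54), Plcxd3 (-1.41), Rasd1 (-1.17), Aurkb (-1.16), a mitotic kinase, Rec114 (-1.0) and Agt (-0.92), which encodes angiotensinogen. Smaller falls were Krt19 (-0.88), Retsat (-0.85), the imprinted RNA H19 (-0.84) and Rab15 (-0.81). The natriuretic peptide gene Nppb rose by 0.42 ± 0.08 (adjusted p = 0.019), while Nppa changed by 0.01 ± 0.06 (adjusted p = 0.938) at the top of the scale, where it could not be resolved. Col1a1 changed by 0.39 ± 0.11 (adjusted p = 0.0811) and Ankrd1, a stretch-responsive gene, rose by 0.29 ± 0.06 (adjusted p = 0.0326).

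**Figure D1:**
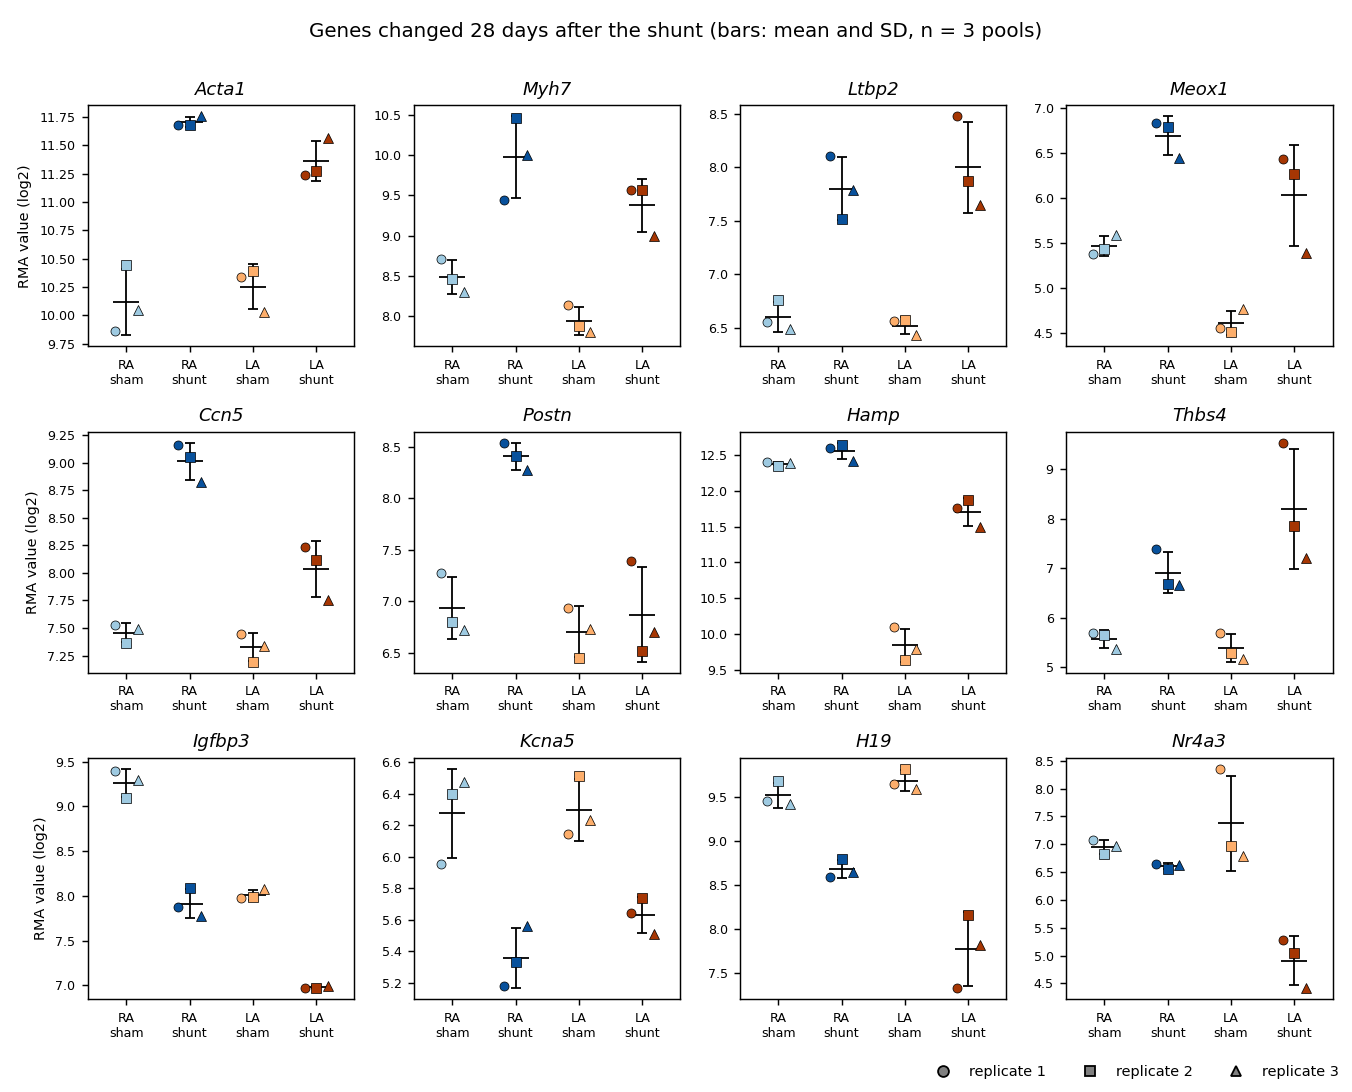
RMA values (log2, vertical axes) of 12 genes on each of the 12 arrays, by group; points are pools, with a symbol per replicate number, and bars are the mean and SD of 3 pools. Acta1, Myh7, Ltbp2 and Meox1 lay higher on every shunt array than on every sham array of the same atrium, Postn did so in the right atrium alone, and Hamp in both atria lay between 9.64 and 12.64.

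Of the 32 measured genes of extracellular matrix and fibrosis, 8 rose, among them Ccn2 (0.98), none fell and 24 did not pass; 18 passed when adjusted over the list alone. The list moved up against all other genes (camera, adjusted p = 1.64e-09; adjusted p = 0.387 with an estimated correlation, as for all 8 lists called here). Of 20 TGF-beta and BMP genes, Bmp4 (0.77), Bmp6 (0.61) and Tgfb1 (0.55) rose and 17 did not pass, against 8 past adjusted over the list alone (camera, adjusted p = 0.0123; adjusted p = 0.387 with an estimated correlation). None of these 3 passed without right atrium shunt replicates 1 or 2 or any 1 right atrium sham replicate, nor did Bmp4 without left atrium sham replicates 1 or 3, and Tgfb1 failed in 10 of 12 exclusions, passing without left atrium shunt replicates 1 or 3. Bmp4 and Tgfb1 did not pass after quantile normalization again, nor Bmp6 as the mean of its probe sets (0.27). In the cardiac stress and fetal programme, Acta1, Myh7, Nppb, Rcan1 (0.46) and Ankrd1 rose of 14 measured, and the list itself did not pass (camera, adjusted p = 0.051).

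Markers of other cells moved too. Of 11 macrophage markers, Aif1 (0.74), Lyz2 (0.68) and Mrc1 (0.59) rose, and 9 passed adjusted over the list alone (camera, adjusted p = 3.76e-05; adjusted p = 0.387 with an estimated correlation); another probe set of Aif1 fell by 0.47. The chemokine gene Ccl2 (0.93) and the endothelial adhesion gene Sele (0.62) rose, and Tnf fell by 0.38. Of 10 endothelial markers Esam rose by 0.37, with 2 past adjusted over the list alone (camera, adjusted p = 0.0104; adjusted p = 0.387 with an estimated correlation). Of 20 interferon response genes Gbp2 rose by 0.39, with 2 past adjusted over the list alone (camera, adjusted p = 0.00965). The camera adjusted p of this list was 0.0513 without right atrium shunt replicate 2 and 0.387 with an estimated correlation. Of 20 oxidative stress genes Cybb, the phagocyte NADPH oxidase, rose by 0.69, with 1 past adjusted over the list alone (camera, adjusted p = 0.0338). The camera adjusted p of this list was 0.0903 without right atrium sham replicate 1 and 0.387 with an estimated correlation.

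Of the 8 atrial cardiomyocyte markers Kcna5 fell and 7 did not pass, with 2 past adjusted over the list alone, and the list moved down (camera, adjusted p = 0.0184; adjusted p = 0.387 with an estimated correlation). Of the 7 ventricular cardiomyocyte markers Myl2, Myl3, Myh7 and Hey2 (0.70) rose, 3 did not pass and 6 passed adjusted over the list alone (camera, adjusted p = 0.000427; adjusted p = 0.387 with an estimated correlation). With replicate 1 as the only right atrium shunt array, an alternative chosen after seeing the data, Myl2 changed by 0.51, Myl3 by 0.65, Myh7 by 0.96 and Hey2 by 0.55. The ventricular markers were uneven over the shunt pools: Myl2 lay at 12.83 and 12.82 on replicates 2 and 3 but at 11.45 on replicate 1, and Irx4, a ventricular transcription factor, at 5.86 and 5.94 against 4.18, where the sham arrays lay between 4.26 and 4.44. Another probe set of Myl2 fell by 0.55. The beta-actin 3' minus 5' difference, which grows as RNA degrades, was on average 0.31 higher on the right atrium shunt than sham arrays, a difference that was not tested. It lay at 1.91 to 2.03 on these shunt arrays and at 1.58 to 1.82 on the sham arrays. The left atrium differed by -0.06, and the GAPDH 3' minus 5' difference by 0.01 in each atrium.

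**Figure D2:**
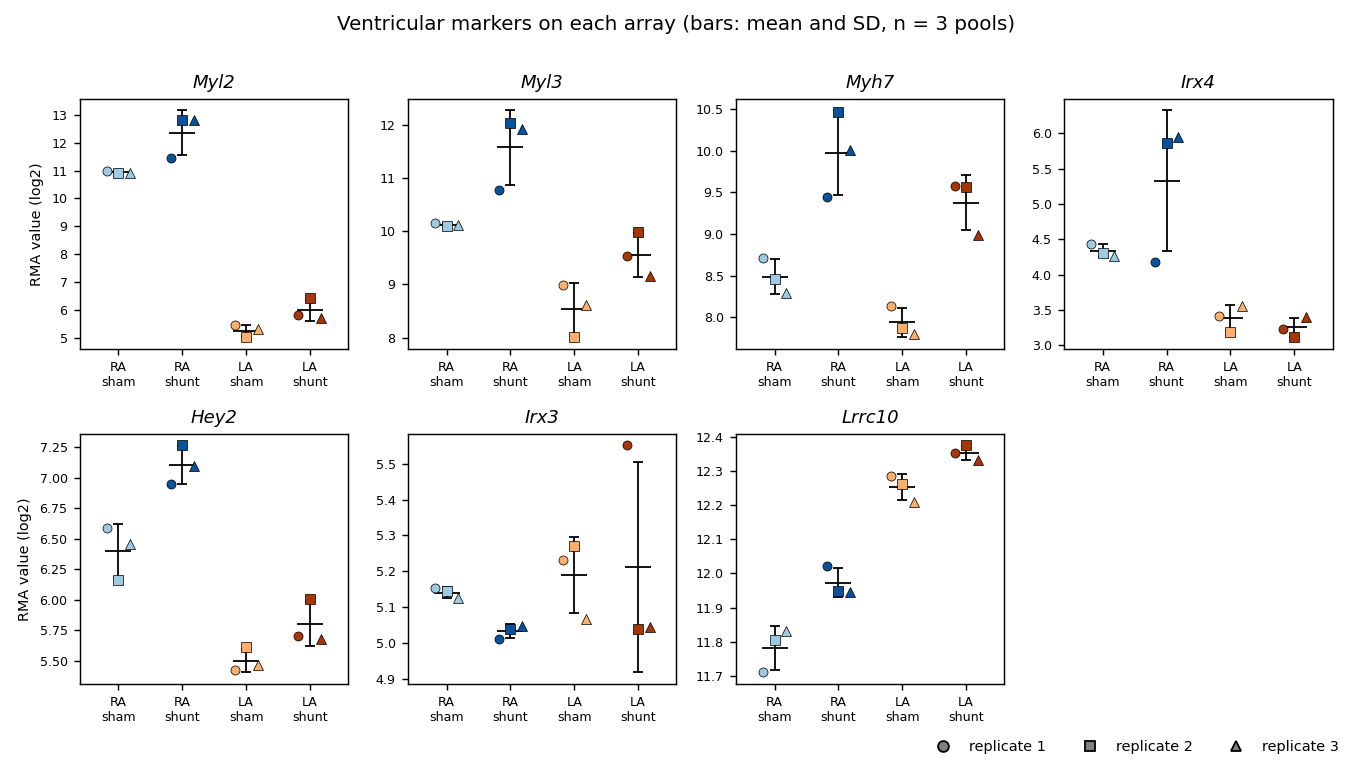
RMA values (log2, vertical axes) of the 7 ventricular cardiomyocyte markers on each array, by group; points are pools, with a symbol per replicate number, and bars are the mean and SD of 3 pools. Right atrium shunt replicates 2 and 3 carried more Myl2, Myl3, Myh7, Irx4 and Hey2 than replicate 1, while Irx3 lay between 5.01 and 5.05 and Lrrc10 between 11.95 and 12.02 on all 3, and Myl2 stayed at or below 6.42 on every left atrium array.

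In all, 923 of 31042 probe sets passed the threshold in the right atrium, 591 higher and 332 lower (64.0% higher), and 46 of them changed at least 2-fold; 6127 had an unadjusted p under 0.05. After quantile normalization again, 664 passed, 352 higher and 312 lower (53.0% higher). Without right atrium shunt replicates 1, 2 or 3 the count was 266, 148 and 442, and without right atrium sham replicates 1, 2 or 3 it was 397, 234 and 312. Without left atrium shunt replicate 3 it was 1631. With replicate 1 as the only right atrium shunt array, lost power alone lowers the count, so none is given. Of 52 named genes past the threshold, 18 stayed past it in every alternative planned in advance that tested them: Sbsn, Acta1, Ccn5, Myh7, Postn, Ltbp2, Gpr15lg, Plcxd3, Igfbp3, Rasd1, Aurkb, Rec114, Kcna5, Retsat, Ccn2, Cox7a1, Ccl2 and Prph. Plcxd3 (group means 3.56 to 6.67) was too dim for the fit without dim probe sets and was not tested in it. Of alternatives added for these genes after seeing the data, a fit of the right atrium arrays alone and 1 probe set per gene kept all 18. As the mean of their probe sets Myl2 (0.44), Bmp6 (0.27), Cybb (0.48), Aif1 (0.14) and Tnf (-0.15) did not pass, and Rab15 (-0.49) did; after quantile normalization again Pilra, Rcan1, Bmp4, Tgfb1, Gbp2, Cybb, Esam, Mrc1 and Tnf did not. Another 33 lost it when at least 1 array was left out, and none changed direction.

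In the left atrium, which receives the raised return from the lungs, Hamp, which encodes the iron regulator hepcidin, rose by 1.87 ± 0.12 (SE, n = 3 pools per group, adjusted p = 4.14e-05). Thbs4, a matricellular thrombospondin, rose by 2.81 ± 0.43 (adjusted p = 0.011) and Ltbp2 by 1.48 ± 0.19 (adjusted p = 0.00359). Thbs4 was uneven over the left atrium shunt pools, at 9.54, 7.85 and 7.21, against 5.17 to 5.71 on the left atrium sham arrays. Myh7 rose by 1.44 ± 0.22 (adjusted p = 0.0124) and Acta1 by 1.11 ± 0.14 (adjusted p = 0.00415). The orphan nuclear receptors Nr4a3 and Nr4a1, immediate early genes, fell. Nr4a3 fell by 2.46 ± 0.32 (adjusted p = 0.00433) and Nr4a1 fell by 1.56 ± 0.27 (adjusted p = 0.0237). H19 fell by 1.93 ± 0.16 (adjusted p = 0.000244). Pdk4, a kinase that restrains glucose oxidation, fell by 0.99 ± 0.08 (adjusted p = 0.000244).

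Further rises were Meox1 (1.42), Kcnip2 (1.36), a subunit of the transient outward potassium channel, Slc16a12 (1.16), Cxcl13 (1.03), Prph (0.97), a neuronal intermediate filament, Ccn2 (0.92) and Smad9 (0.89). Further falls were Gpr15lg (-1.71), Rasd1 (-1.52), Aurkb (-1.47), Col6a6 (-1.30), Fgg (-1.16), Scn4b (-1.15), a sodium channel subunit, Iqgap2 (-1.10), Retsat (-1.08) and Epb41l3 (-1.05). Nppb rose by 0.60 ± 0.08 (adjusted p = 0.00486). Nppa changed by 0.05 ± 0.06 (adjusted p = 0.78), again at the top of the scale, Postn by 0.16 ± 0.21 (adjusted p = 0.78), Ankrd1 by 0.22 ± 0.06 (adjusted p = 0.132) and Col1a1 by -0.04 ± 0.11 (adjusted p = 0.92).

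Of 24 genes of fatty acid uptake and oxidation Pdk4 fell and 23 did not pass, with 4 past adjusted over the list alone, and the list moved down (camera, adjusted p = 1.80e-07; adjusted p = 0.378 with an estimated correlation). On left atrium shunt replicate 3, the array that stood apart, 21 of these 24 genes lay above both other arrays of the group (median 0.17), while the medians of the matrix (-0.36), TGF-beta and BMP (-0.24) and immediate early lists (-0.24) lay below them. Of 32 matrix genes Thbs4, Ltbp2 and Ccn2 rose, 29 did not pass and 10 passed adjusted over the list alone (camera, adjusted p = 8.51e-06; adjusted p = 0.575 with an estimated correlation). Of 14 genes of the cardiac stress and fetal programme Myh7, Acta1, Nppb and Uchl1 (0.72) rose, and 7 passed adjusted over the list alone (camera, adjusted p = 5.38e-05; adjusted p = 0.252 with an estimated correlation). No TGF-beta or BMP gene of 20 passed, with Bmp4 at 0.84 and Smad7 at 0.53, against 7 past adjusted over the list alone (camera, adjusted p = 0.00713; 0.0813 without left atrium shunt replicate 2; adjusted p = 0.414 with an estimated correlation). None of 20 oxidative stress genes passed, with 3 past adjusted over the list alone (camera, adjusted p = 0.0409; adjusted p = 0.378 with an estimated correlation). That list passed in 6 of 12 exclusions of an array. It did not pass without right atrium shunt replicate 1, left atrium shunt replicates 1 or 2 or any left atrium sham replicate, where its adjusted p reached 0.238.

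Of 20 immediate early genes Nr4a3 and Nr4a1 fell and 18 did not pass, with 10 past adjusted over the list alone (camera, adjusted p = 5.38e-05; adjusted p = 0.468 with an estimated correlation). The left atrium sham arrays carried the highest mean levels of this list, 7.74, 7.06 and 7.23, against 6.59 to 6.88 on the left atrium shunt arrays and 6.57 to 6.84 on the right atrium arrays. Of 13 heat shock genes Hspa1a fell by 0.60, with 6 past adjusted over the list alone (camera, adjusted p = 0.000266; adjusted p = 0.252 with an estimated correlation). Of 11 neuronal markers Prph and Uchl1 rose, with 2 past adjusted over the list alone (camera, adjusted p = 5.38e-05; adjusted p = 0.378 with an estimated correlation). Left atrium shunt replicate 3, the array that stood apart, carried more of other neuronal and of fat markers than the other 2 arrays of its group, with Nefl at 4.35 against 3.17 and 3.24 and the brown fat gene Ucp1 at 7.56 against 4.22 and 4.66. Of 7 ventricular markers Myh7 rose and 6 did not pass, with 2 past adjusted over the list alone (camera, adjusted p = 0.00328; adjusted p = 0.378 with an estimated correlation).

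Among channels, the transient outward subunit gene Kcnd2 fell by 0.70 and the calcium channel gene Cacna1d rose by 0.56. Cacna1d did not pass as the mean of its probe sets (0.17) or without left atrium shunt replicate 1 or left atrium sham replicates 2 or 3, and Kcnd2 not without left atrium shunt replicate 2 or left atrium sham replicates 2 or 3. Kcnip2 (0.90), Smad9 (0.59) and Nr4a3 (-1.23) changed less as the mean of their probe sets and still passed. In all, 233 probe sets passed, 88 higher and 145 lower, with 36 changed at least 2-fold and 4207 at an unadjusted p under 0.05. Without left atrium shunt replicate 3 the count was 554, 289 higher and 265 lower, and without left atrium shunt replicate 2 it was 116. Of those 554, 42.8% lay on the shunt side of the midpoint between groups on the array left out, against 69.4% and 76.7% of the calls made without replicate 1 or 2. Without left atrium sham replicates 1, 2 or 3 it was 151, 84 and 77. Without right atrium shunt replicates 2 or 3 or right atrium sham replicate 3 it was 139, 136 and 152. In a fit of the left atrium arrays alone it was 13, 1 higher and 12 lower. Of 34 named genes past the threshold, 26 lost it in that fit, which was added for the named genes after seeing the data, and 15 when at least 1 array was left out. Those past it in all alternatives that tested them were Hamp, H19, Gpr15lg, Rasd1, Aurkb, Igfbp3, Fgg and Pdk4. Fgg (group means 3.94 to 5.41) was too dim for the fit without dim probe sets and was not tested in it. Ltbp2, Acta1, Prph, Ccn2, Nr4a3, Col6a6, Iqgap2, Retsat, Epb41l3, Nppb and Hspa1a lost it in the fit of the left atrium arrays alone and in no other.

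Both atria shared part of their response. Acta1, Myh7, Ltbp2, Meox1, Ccn2, Ccn5, Nppb and Prph rose in each, and Gpr15lg, Rasd1, Aurkb, Igfbp3, H19, Retsat and Pdk4 fell in each. Of the 92 probe sets past the threshold in both, 44 were higher in both, against 1.68 for independent lists, 47 were lower in both, against 1.55, and 1, of the zinc finger gene Zfp292, went opposite ways. The comparisons shared no arrays, but 1 estimate of spread per probe set served both, so independent lists give too low an expectation. Of the 923 right atrial calls, 703 had the same sign in the left atrium, with a median left to right ratio of 29.2%. Of the 233 left atrial calls 199 had the same sign in the right, with a median right to left ratio of 50%. Across all 14217 genes, which are not independent replicates, the effects correlated with a Pearson r of 0.328 and a Spearman rho of 0.173.

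**Figure D3:**
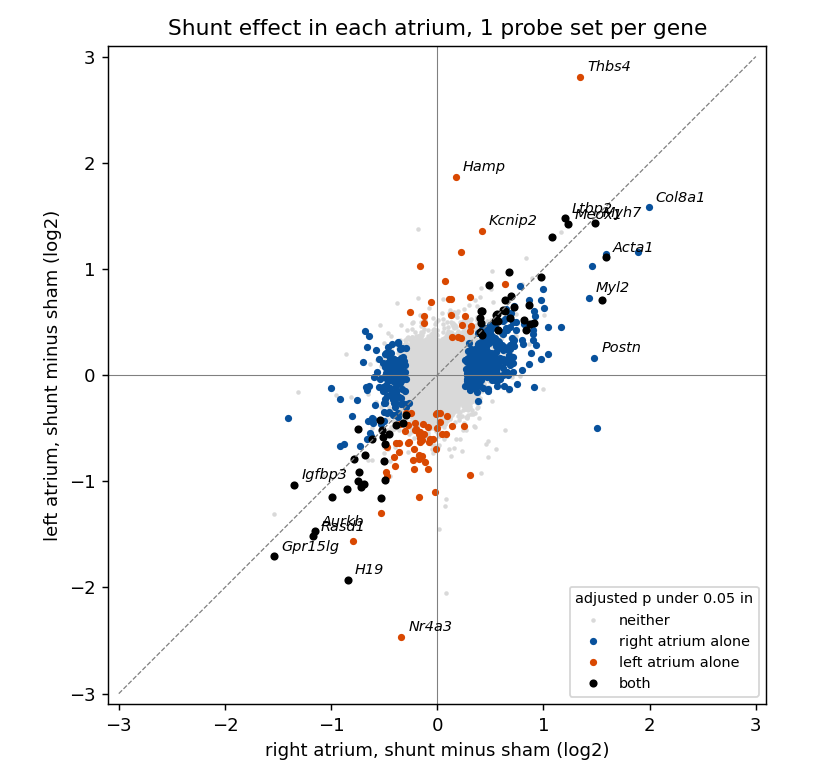
Shunt minus sham effect (log2) in the right atrium (horizontal axis) and left atrium (vertical axis); each point is a gene, coloured by the atria in which its adjusted p was under 0.05, and the dashed line marks equal effects. Acta1 lies in the upper right and Gpr15lg in the lower left, while Postn lies near 0 for the left atrium and Hamp near 0 for the right.

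Averaged over both atria, 1198 probe sets passed, 716 higher and 482 lower. The lists called were those of matrix (13 of 32 genes rose; adjusted p = 0.359 with an estimated correlation), stress and fetal programme (7 of 14 rose; adjusted p = 0.258 with an estimated correlation), TGF-beta and BMP (5 of 20 rose; adjusted p = 0.28 with an estimated correlation). Others were those of macrophage markers (2 of 11 rose; adjusted p = 0.369 with an estimated correlation) and interferon (2 of 20 rose; adjusted p = 0.369 with an estimated correlation). Also called were the ventricular (4 of 7 rose; adjusted p = 0.258 with an estimated correlation) and oxidative stress lists (2 of 20 rose; adjusted p = 0.258 with an estimated correlation). Downward came the fatty acid (5 of 24 fell; adjusted p = 0.369 with an estimated correlation), heat shock (2 of 13 fell; adjusted p = 0.28 with an estimated correlation) and atrial cardiomyocyte lists (2 of 8 fell; adjusted p = 0.258 with an estimated correlation). Adjusted over the list alone, 19 matrix, 8 stress, 12 TGF-beta and BMP, 8 macrophage, 4 interferon, 5 ventricular, 5 oxidative stress, 6 fatty acid, 3 heat shock and 3 atrial genes passed. Without left atrium shunt replicate 3 the count of probe sets was 2018, without left atrium shunt replicate 2 or sham replicates 2 or 3 it was 787, 779 and 717, and without right atrium shunt replicates 1 or 2 or sham replicates 2 or 3 it was 754, 672, 711 and 742. As above, no count is given for replicate 1 as the only right atrium shunt array.

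Whether the shunt acted differently on the atria was tested as an interaction. Of the named genes past the threshold Hamp differed most: it rose in the left atrium from 9.84 ± 0.23 to 11.71 ± 0.19 (SD, n = 3 pools) and changed in the right from 12.38 ± 0.03 to 12.56 ± 0.12, a difference of effects of 1.69 ± 0.17 (SE, adjusted p = 0.00753). The chemokine receptor genes Cxcr5 (0.93 ± 0.11, adjusted p = 0.0235) and Ccr6 (0.72 ± 0.10, adjusted p = 0.0441) and the acylphosphatase gene Acyp2 (0.83 ± 0.12, adjusted p = 0.0441) also had higher effects in the left atrium. Ccr6 lay low, at group means of 3.62 to 4.25, where the lower quartiles of the arrays were 3.86 to 3.99. Genes with the next smallest p did not pass, among them Slc22a8 (1.01, adjusted p = 0.0507), Trim72 (-0.76, adjusted p = 0.0587), Afm (0.73), Arid1b (0.59), Mllt11 (-0.62) and Iqgap2 (-1.08, adjusted p = 0.0846). Postn (-1.31, adjusted p = 0.141) and Nr4a3 (-2.12, adjusted p = 0.141), each called in 1 atrium, were not shown to differ between atria. Nor were Nppa (0.03), Nppb (0.18), Col1a1 (-0.42), Ankrd1 (-0.07), Myh7 (-0.05) and Acta1 (-0.48), with adjusted p from 0.263 to 0.959.

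Lists were called for the interaction without any member past the threshold. Immediate early genes moved lower in the left atrium (camera, adjusted p = 0.000238; adjusted p = 0.53 with an estimated correlation; 3 of 20 past adjusted over the list alone), with Atf3 at -2.13. Neuronal markers moved higher (camera, adjusted p = 0.00094; adjusted p = 0.53 with an estimated correlation; 0 of 11 past adjusted over the list alone), with Nefl at 0.73 (0.34 without left atrium shunt replicate 3), whose left atrium shunt values were 3.17, 3.24 and, on replicate 3, 4.35. The adipocyte list (camera, adjusted p = 0.0422; adjusted p = 0.687 with an estimated correlation; 0 of 8 past adjusted over the list alone) moved higher and was called in 5 of 12 exclusions. It was not called without left atrium shunt replicates 2 or 3, left atrium sham replicate 1, right atrium shunt replicates 1 or 3 or right atrium sham replicates 1 or 3, with an adjusted p of up to 0.126, reached without left atrium shunt replicate 3. The fatty acid list (camera, adjusted p = 0.0422; adjusted p = 0.698 with an estimated correlation; 1 of 24 past adjusted over the list alone) moved lower and was called in 4 of 12 exclusions. It was not called without left atrium shunt replicates 1 or 2, any left atrium sham replicate, right atrium shunt replicates 2 or 3 or right atrium sham replicate 1, with an adjusted p of up to 0.246. In all, 8 probe sets passed, 7 with the higher and 1 with the lower effect in the left atrium (87.5% higher), and 4467 had an unadjusted p under 0.05; after subtraction of array medians 4 passed, 3 higher and 1 lower (75% higher). Without right atrium shunt replicate 1 the direction turned, with 3 higher and 4 lower (42.9% higher). So it did with the replicate number as a block, where 3 passed, 1 higher and 2 lower, and Cxcr5, Ccr6 and Acyp2 were not called. The count was 21 without left atrium shunt replicate 3 and 0 (limma) without right atrium sham replicate 1. It was 1 without right atrium shunt replicate 2 or left atrium sham replicates 2 or 3, 2 without right atrium sham replicate 2, 3 without left atrium shunt replicate 2 and 4 without left atrium sham replicate 1. Of the 4 named genes past the threshold Hamp, at 1.59 to 1.82 in the alternatives run, lost its call in 1 of 12 exclusions, without right atrium sham replicate 1. Cxcr5 (0.51 to 1.01, the lowest as the mean of its probe sets, where it did not pass) lost it in 5 of 12, without right atrium shunt replicate 2, right atrium sham replicates 1 or 2 or left atrium sham replicates 2 or 3. Acyp2 (0.77 to 0.91) lost it in 10 of 12 and kept it without replicate 3 of either shunt group, and Ccr6 (0.63 to 0.77) lost it in 11 of 12 and kept it without left atrium shunt replicate 3. Neither passed after subtraction of array medians, nor Ccr6 after quantile normalization again or with trend and robust options, while their effects stayed of similar size.

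In sham animals the atria differed widely. Higher in the left atrium were Adamts8, a secreted protease, by 3.47 ± 0.15 (SE, n = 3 pools per group, adjusted p = 6.92e-08), and Pi16, a fibroblast marker, by 3.0 ± 0.22 (adjusted p = 1.31e-06). Ccl21 was higher by 2.91 ± 0.24 and the Wnt antagonist Sfrp1 by 1.90 ± 0.10 (adjusted p = 2.25e-07). Lower in the left were Myl2, the ventricular regulatory light chain (-5.69 ± 0.30, adjusted p = 1.94e-07), the chemokine gene Cxcl13 (-3.69 ± 0.19) and Hamp (-2.54 ± 0.12, adjusted p = 1.08e-07). So were Kcnip2 (-2.31 ± 0.22) and the sinus venosus factor Shox2 (-1.64 ± 0.14, adjusted p = 3.54e-06).

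**Figure D4:**
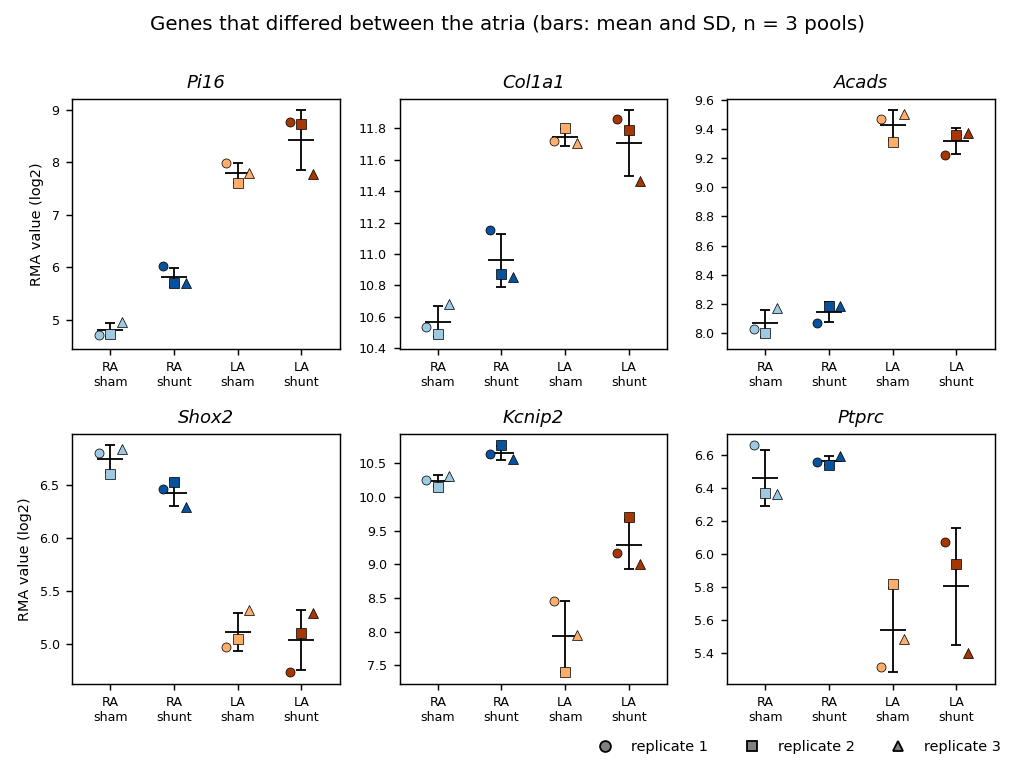
RMA values (log2, vertical axes) of 6 genes on each of the 12 arrays, by group; points are pools, with a symbol per replicate number, and bars are the mean and SD of 3 pools. Pi16, Col1a1 and Acads lay higher, and Shox2 and Kcnip2 lower, on every left than on every right atrium array.

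Other large differences upward were Obp3 (2.38), Adh1c (2.38), Prrc2a (2.32), Cnbd2 (2.02), Zc2hc1a (1.95), Htr2a (1.88) and Lbp (1.84). Downward they were Plcxd3 (-2.70), Ebf2 (-2.46), Zbtb41 (-2.44), Arxes1 (-2.33), Zfp536 (-2.29), Smad9 (-2.19), Mga (-2.19) and Tafa2 (-2.12). As the mean of their probe sets Myl2 (-3.20), Kcnip2 (-1.11), Shox2 (-0.62), Smad9 (-1.15), Zfp536 (-0.86), Mga (-1.45), Htr2a (0.87), Cnbd2 (1.02) and Zc2hc1a (1.19) differed less and still passed. Ankrd1 was higher by 0.22 (adjusted p = 0.0155), but did not pass without right atrium sham replicate 3 or left atrium sham replicate 1, nor as the mean of its probe sets (0.04). Nppa (-0.03), Nppb (-0.14), Postn (-0.23), Myh7 (-0.55) and Acta1 (0.14) did not pass, although another probe set of Myh7 was higher by 0.90 and passed and the mean of its probe sets was 0.17. Of 24 fatty acid genes 15 were higher in the left atrium and none lower, with Acads (1.36), Hadha (0.59; 0.15 and not past as the mean of its probe sets) and Ech1 (0.52) among them, 17 past adjusted over the list alone (camera, adjusted p = 0.000599; adjusted p = 0.793 with an estimated correlation). Of 20 immediate early genes 11 were higher and none lower, with Atf3 (2.00, or 1.29 without left atrium sham replicate 1), Fosb (1.22, or 0.72 without it), Jun (1.12) and Ier2 (1.02), 12 past adjusted over the list alone (camera, adjusted p = 0.00882; adjusted p = 0.824 with an estimated correlation). Fry, which compares no other genes, called 20 of 37 lists.

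The lists not called by camera held many calls of their own, but so did the genes at large, of which 5346 of 14217 passed. Camera did not find these lists to differ from the other genes. Of 17 patterning genes 8 were higher, with Nkx2-5 (1.03), and 3 lower, Shox2, Meis2 (-1.85) and Hey1 (-1.06), with 12 past adjusted over the list alone. The median of that list was 0.23, as its test upward, and its mean -0.02. Of 32 matrix genes 14 were higher, Col1a1 (1.17) and Fmod (1.11) among them, and 3 lower, among them Lox (-1.29), with 17 past adjusted over the list alone. Of 8 mesothelial markers 5 were higher, among them Msln (1.39) and Krt19 (0.94), and of 8 smooth muscle markers 5, among them Smtn (1.11) and Tagln (0.85), with 5 of each list past adjusted over the list alone. Of 9 T and NK cell markers 4 were lower, among them Nkg7 (-0.51), with 5 past adjusted over the list alone. Of 7 ventricular markers Myl2, Myl3 (-1.60), Irx4 (-0.95) and Hey2 (-0.90) were lower and 1 higher, with 6 past adjusted over the list alone. Irx4 did not pass in 8 of 12 exclusions, without any 1 replicate of either sham group or left atrium shunt replicates 1 or 2, nor with trend and robust options or as the mean of its probe sets (-0.31).

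In sham animals 11214 probe sets passed (36.1%), 6228 higher and 4986 lower in the left atrium, and 1027 differed at least 2-fold. Array handling moved with the chamber: the poly-A control probe sets, which report RNA added during labelling, lay lower on all 6 left than on all 6 right arrays, by 0.45 on average (exact two-sided permutation test, p = 0.00216, adjusted p = 0.00271 over 5 control measures). The beta-actin 3' minus 5' difference was 1.28 ± 0.09 on left and 1.81 ± 0.19 on right arrays (SD, exact permutation p = 0.00216, adjusted p = 0.00271). The GAPDH 3' minus 5' difference (-0.15) and the cre control added at hybridisation (-0.44) were also lower on all left than on all right arrays (exact permutation p = 0.00216, adjusted p = 0.00271 for each), while the bioB and bioC hybridisation controls differed by -0.07 (exact permutation p = 0.413, adjusted p = 0.413). Since every array of a chamber lay on the same side in all of these measures except bioB and bioC, chamber and handling cannot be told apart for the count as a whole. The differences of Myl2 (-5.69) and Adamts8 (3.47) were far larger than these control shifts. Myl2 is a ventricular marker, and whether ventricular tissue in the right atrium pools made part of its difference was not tested. Of 476 genes with at least 2 probe sets past the threshold at 0.5 log2 or more, 15.1% had probe sets with opposite signs.

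After the shunt the atria still differed in the same way at most of these genes: Pi16 (2.62), Adamts8 (2.71), Sfrp1 (1.74) and Nkx2-5 (0.92) were higher in the left atrium and Shox2 (-1.39; -0.50 as the mean of its probe sets), Meis2 (-1.98) and Myl2 (-6.38; -3.20 as that mean) lower. Hamp was lower by 0.85 where it had been lower by 2.54 in sham animals, the change tested by the interaction. In both conditions 3965 probe sets were higher in the left atrium, against 1260 for independent lists, 3499 were lower, against 869, and 41 went opposite ways. Here too both comparisons used the same estimate of spread, so independent lists give too low an expectation. Of 11 macrophage markers 6 were lower in the left atrium, among them Cd163 (-1.19), Ptprc (-0.76) and Aif1 (-0.66), with 6 past adjusted over the list alone (camera, adjusted p = 0.029; adjusted p = 0.877 with an estimated correlation). Aif1 did not pass as the mean of its probe sets (-0.20). That list was not called without left atrium shunt replicate 3 (adjusted p = 0.11), the array that stood apart, on which its median lay 0.56 below the other 2 arrays. In all 11690 probe sets passed, 6280 higher and 5410 lower. With probe sets below the median mean left out the direction turned, with 3673 higher and 4505 lower. Here too no count is given for replicate 1 as the only right atrium shunt array.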

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

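The tests of array handling, RNA integrity, the interaction with mean effects removed, ventricular myocardium, fat and nerve tissue and RNA degradation, and the shares of 2-fold changes and of right atrial calls in the test of a wrong label, were chosen after the results were seen. The test of a wrong label on all called probe sets and the other splits of the arrays were planned before.

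By the interaction test, the effect of the shunt differed between atria for 8 probe sets. It was higher in the left atrium for Hamp (1.69), Cxcr5 (0.93), Zfp292 (0.84), Larp4b (1.03), Ccr6 (0.72), Acyp2 (0.83) and an unnamed probe set (0.68), and lower for another unnamed probe set (-1.15). Cxcr5, Ccr6, Acyp2 and Larp4b had lower mean values in right atrium shunt than sham pools and higher ones in left atrium shunt than sham pools. The effect also differed for 4 lists, with median differences of -0.41 for immediate early genes, 0.48 for neuronal markers, 0.54 for adipocyte markers and -0.15 for fatty acid genes. None of these 4 calls held with an estimated correlation (camera, adjusted p = 0.53, 0.53, 0.687 and 0.698), and the adipocyte and fatty acid lists were called in 5 and 4 of 12 exclusions of an array. Outside the comparisons, the control probe set for the 3' end of hexokinase was 0.67 ± 0.13 higher on right atrium shunt than sham arrays (limma, SE, adjusted p = 0.0105 over 57 control probe sets). The 5' set differed by 0.32 (limma, adjusted p = 0.783) and the middle set by 0.09 (limma, adjusted p = 0.792).

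Other splits of the arrays were tried for each count. For the shunt effect in the right atrium (923) and left atrium (233) and the chamber difference in sham (11214) and shunt animals (11690), 10 splits are too few for a share under 0.05. The highest other counts were 0, 0, 0 and 3, and 1 of 10 splits, the real one, reached each real count. For the mean over both atria 1 of 100 splits, the real one, reached 1198, with 342 as the highest other, a share under the planned bound of 0.05. For the interaction 2 of 100 splits reached 8, but these splits decide nothing: the shared shunt effect enters either their spread or, as in the split that gave 342 and exchanged 4 left atrial labels alone, their contrast, a structure of the arrays. With the mean effects of chamber and shunt removed first, 1 of 100 splits, the real one, reached 8, with 1 as the highest other. These splits did not keep right and left arrays of the same number together, and the test was chosen after the results were seen. The count also ran from 0 to 21 with an array left out, so chance is not excluded for these 8 probe sets.

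The large number of differences between atria went with differences in array handling. The poly-A controls, added during labelling, were lower on left arrays (-0.45, exact permutation p = 0.00216), and so were the cre controls added at hybridisation (-0.44) and the 3' minus 5' differences of beta-actin (-0.53) and GAPDH (-0.15), with the same p. No table argues against either labelling or RNA integrity as a source of part of the count. All arrays of a chamber lie on 1 side in these 4 measures, so for the count as a whole handling and chamber cannot be told apart; the bioB and bioC controls differed by -0.07 (exact permutation p = 0.413), and Myl2 (-5.69) by far more than any of these controls. An unnamed probe set differed by more still in sham animals, at a mean of 13.54 in the right and 3.47 in the left atrium (-10.07). Such single large differences do not settle the count as a whole. How much of the count reflects a biological difference between the chambers stays open, untested.

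Ventricular markers rose unevenly in the right atrium: 6 of 7 were higher after the shunt, and 6 of 7 were lowest on replicate 1 among the shunt arrays, Irx3 by little (5.01 against 5.04 and 5.05). More ventricular myocardium in pools 2 and 3 is a candidate explanation that this ordering is consistent with, and the labels name ventricles besides atria in the tissue entry of these samples. A response of the atrial muscle to the shunt that differed between pools stays open, untested. For the rise of Myh7 in the left atrium the tables argue against ventricular myocardium: Myl2 reached at most 6.42 on the left atrium shunt arrays, against 11.24 needed for such a rise by the ratio seen in the right atrium. There a response of the muscle itself stays open as a hypothesis, untested.

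Left atrium shunt replicate 3 stood apart, and its 3' minus 5' differences, of beta-actin (1.39) and GAPDH (0.28), each lay 0.074 above the highest other left atrium array, which leaves degraded RNA open. Fat and nerve tissue in the pool may contribute. Its adipocyte markers lay 0.72 (median of 8) above the other 2 arrays and its neuronal markers 0.38 (median of 11). Both, like its fatty acid genes (0.17, median of 24), lay above all of 10000 random lists. Its macrophage (-0.56), mesothelial (-0.43), matrix (-0.36), immediate early (-0.24) and TGF-beta and BMP lists (-0.24) lay below all of them. The random lists were matched on mean level alone. Genes of a list can vary together (estimated correlation 0.64 for adipocyte and 0.23 for neuronal markers), which makes such extreme positions easier to reach. These positions therefore do not decide which tissue was in the pool. The planned test of a wrong label came out on the side of one: 42.8% of the 554 probe sets called without this array lay on the shunt side of the midpoint on it, against 69.4% and 76.7% for the other shunt arrays left out likewise and 6.49% to 18.5% for the sham arrays. Its bound of 50% was wide, since a pool of sham tissue alone would be expected near the sham arrays. Shares chosen afterwards placed this array between the shunt and sham arrays. Of the 174 also called in the right atrium, a comparison that shares no arrays, 51.1% lay on the shunt side. The other shunt arrays had 93.9% or more and the sham arrays at most 4.55%. Of the 62 changed at least 2-fold it was 56.5%, against 77.8% and 84% on the other shunt and 4.17% to 10.7% on sham arrays. The largest changes alone exclude nothing. Of all 923 right atrial calls it was 48.0%, against 73.6% and 77.1% on the other shunt and 28.7% to 31.5% on sham arrays. Except for these 923, each array left out had its own list of probe sets. A wrong label is therefore not excluded. A pool with tissue of both kinds and a weaker response to the shunt also stay open, untested, and left atrial shunt values rest in part on this array.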

How the results depend on the processing

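The fits keeping replicate 1 alone of the right atrium shunt group were chosen after seeing the data. So were, for the named genes, those of only the groups compared and of 1 probe set per gene, and no others were. The fits keeping replicate 1 alone assume that this array varies like the other groups, and they lose power with the smaller group. Their values are included in the totals that follow. Of the values compared with the reported ones, 3986 kept direction and side of the threshold or size, 469 were no longer past it, 56 came past it, 80 moved and 13 reversed. Where no cause is given, the cause was not tested. The number of arrays limits what was called, and probe sets near background or the top of the scale show little change.

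For the shunt effect in the right atrium the count of 923 became 2352 with array weights and 1415 with only the groups compared. It ranged from 148 to 1631 with an array left out. In the left atrium 233 became 453 without dim probe sets, 485 with trend and robust options, 370 with array weights and 13 with only the groups compared, and ranged from 77 to 554. With only the groups compared 26 of 34 named left atrial and 3 of 52 right atrial calls were lost, and with 1 probe set per gene none of either. The mean count of 1198 became 1867 with array weights and 239 keeping only replicate 1, and ranged from 672 to 2018. The interaction count of 8 (limma, with 4467 at an unadjusted p under 0.05 in all arrays) became 19 without dim probe sets and 4 with array medians subtracted. It became 15 with trend and robust options and 15 with array weights, and ranged from 0 to 21 with an array left out. The chamber count became 5621 with 1 probe set per gene and 5804 with gene means in sham animals, and 6097, 6249 and, keeping only replicate 1, 4797 in shunt animals; with 1 value per gene fewer features were tested.

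Gene lists called by camera numbered 0 in all 6 comparisons with an estimated correlation. Fry called 15 in the right atrium, 5 in the left, 0 in the interaction, 20 between chambers in sham and 16 in shunt animals. For the interaction, 1 was called without dim probe sets, 2 after quantile normalization again and 2 to 7 with an array left out. Between chambers in shunt animals, where 1 was called, it was 0 without dim probe sets, 5 after quantile normalization again, 4 with gene means and 0 to 9 with an array left out. Without dim probe sets the correlation of the effects in both atria was 0.474 (Pearson) and 0.331 (Spearman). Uncalled values that reversed were Nppa in the right atrium, -0.020 after quantile normalization again and -0.0044 to 0.023 with an array left out; Col1a1 in the left, 0.026 with array weights and -0.11 to 0.082 with an array left out; Postn in the left, -0.095 to 0.34 with an array left out; Myh7 between chambers in sham animals, 0.17 with gene means; and, for the interaction, Ankrd1, 0.021 with gene means, and Myh7, 0.000919 after quantile normalization again, 0.48 keeping only replicate 1 and -0.31 to 0.20 with an array left out.

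Replicate numbers were not taken to pair the arrays, since the labels do not say that they do, and pairing of right and left arrays stays open. Right and left arrays of the same number correlated at 0.0789 to 0.148 in their deviations, 3 of 6 pairs over 0.1. Those of different numbers correlated at -0.0886 to -0.0116, and shunt and sham arrays of the same number at -0.0765 to -0.00595. Each of the 6 right and left pairs was the best match for both its arrays, a hint from the data and not the design. With the replicate number over all 4 groups as a block, the counts were 762 in the right atrium (672 shared), 248 in the left (187 shared) and 1146 for the mean. That block also ties shunt to sham arrays of a number, so the 1146 does not test pairing of right and left arrays. With the number within each operation as a block, the counts were 3 for the interaction (1 higher and 2 lower, 2 shared) and 11199 and 11601 between chambers in sham and shunt animals. Of the named interaction genes Cxcr5, Ccr6 and Acyp2 were not called with the block. With the block 6 gene lists were called between chambers in shunt animals.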

Other observations

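The genes in this part were chosen after their values were seen, and the part reports no tests beyond the limma fit. Among the 68 named genes with a probe set past the threshold in both atria were some outside the lists described. The basement membrane collagen Col4a2 rose by 0.91 in the right and 0.49 in the left atrium, and Tnfrsf11b, the decoy receptor osteoprotegerin, by 0.86 and 0.66. The chemokine receptor Cxcr4 rose by 0.68 and 0.54, and Thy1, a surface protein of fibroblasts and other cells, by 0.63 and 0.60. In the left atrium each of these 4 lost its call in at least 7 of 12 exclusions of an array, among them those of left atrium shunt replicate 1 and of each left atrium sham replicate, and in a fit of the left atrium arrays alone. In the right atrium Thy1 lost it without right atrium shunt replicates 1 or 2 or right atrium sham replicates 1 or 2.

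Immediate early genes were spread unevenly over the left atrium sham pools. Atf3 lay at 7.29, 5.69 and 4.66 on these 3 arrays and at 3.73 to 3.96 on the left atrium shunt arrays, and Nr4a3 at 8.35, 6.98 and 6.80 against 4.42 to 5.27. On left atrium shunt replicate 3, 226 probe sets lay at least 2-fold above both other arrays of its group and 79 as far below. Of the 226, 74.8% named no single gene, against 32.9% of all probe sets. Genes with at least 2 probe sets past the threshold at 0.5 log2 or more had opposite signs among them in 2 of 17 cases for the right atrium shunt effect and in 0 of 12 for the left. Uncalled probe sets of the other sign were those of Bmp6 (-0.15) and Tnf (0.09) for the right atrium shunt effect, Cacna1d (-0.24) for the left, Irx4 (0.32), Hadha (-0.08) and Ankrd1 (-0.14) between chambers in sham animals, Aif1 (0.26) and Shox2 (0.10) in shunt animals, and Nr4a3 (0.10), Arid1b (-0.11) and Ankrd1 (0.11) for the interaction, where another probe set of Cxcr5 gave 0.10.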
